A study of Mus musculus with 12 samples.

How the data were processed

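The values were FPKM (fragments per kilobase of gene, scaled by library size), in a table the authors deposited with 52636 genes and 12 libraries. Reads were aligned with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, both named without their settings in the submitters' processing notes. DESeq2 1.16.1 and edgeR 3.18.1 are also listed, with no role given, in the submitters' processing notes. Libraries were prepared by a standard Illumina method, per the labels' protocols, and whether they keep the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The processing notes name build mm8, but of the 52636 gene identifiers 52403 are in GENCODE release M21 for GRCm38, and 49909 of these (95.2%) have the same coordinates there. Coordinates are printed as in the deposited table and read as GRCm38.

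Multiplying FPKM by gene length gave whole multiples of 1 step per library, with 100% of nonzero values whole within 0.001 reads. The recovered reads assigned to genes ranged from 18914607 to 26530485 per library. The implied totals behind the deposited FPKM differed from these by factors from 0.952 to 1.11, whose origin is not stated. An FPKM of 1 corresponded to between 18.7 and 27.2 reads per kilobase of gene, so values near the expression minimum rest on few reads.

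Groups were taken from the library titles. The 12 pairs of replicates within groups differed by more than sampling noise (chi-square per gene from 5.63 to 96.5), so none was treated as a library deposited again. This check does not show that the libraries came from separate animals. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(FPKM + 1), for the 13540 genes with FPKM of at least 1 in at least 3 of 12 libraries. All 12 libraries entered 1 fit of 4 group means, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, adjusted within each comparison. Changes on this scale understate those of low genes. Genes low in control can pass the expression minimum through libraries with cisplatin alone. Among genes low in control, those that rise are thus more likely to be tested. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so none was used for single genes. There were 6 comparisons: cisplatin, PCN and cisplatin+PCN against control, cisplatin+PCN against cisplatin and against PCN, and the interaction.

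Gene lists for kidney cell types, injury, drug response, metabolism and possible admixed tissue (32 lists) were tested with camera in limma at a preset inter-gene correlation of 0.01, for the 26 lists with at least 5 tested members. The alternative with an estimated correlation is given beside each list that passed. The groups, tests, lists, alternatives and rule for named genes were fixed before the data were examined. The rule named, per main comparison, up to 10 genes in each direction with the largest change among protein-coding genes that passed with non-overlapping groups (5 for the interaction), up to 3 members of each list that passed, and a fixed panel of injury, PXR and tubule genes. The text names a part of these, with other genes marked as picked after their values were seen or given as list members. Some genes that the rule names are not reported here.

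The slope of the cisplatin effect with PCN on that without was the covariance of 2 effects that share no library, divided by the variance of the second less its mean squared standard error. Correlation across genes with shared libraries was set beside 100 simulations of unchanged groups. Counts of shared calls were set beside 100 simulations each of unchanged groups and of a cisplatin effect with cisplatin+PCN equal to cisplatin, drawn from normal distributions with each gene's SD per group. Each gene was drawn independently, so genes do not vary together in these simulations. The cisplatin libraries were also split, 1 against 2, between the 2 changes that use them, with limma's test on 5 groups, where a lone library is assumed to vary like the others. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, 3 other scalings (median of ratios, quantile, and rescaling without the 50 highest and the mitochondrially encoded genes), only the groups compared, array weights, a replicate block, limma-voom on the recovered reads, and leaving out each library.

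The procedures were tested on simulated data in which 200 genes were changed, of which 197 passed the expression minimum for PCN against control and 198 for cisplatin+PCN against cisplatin. For PCN against control (13340 genes) they recovered 43.3% of genes changed 1.5-fold, 72.3% at 2-fold and 86.2% at 4-fold, with 13 false calls. For cisplatin+PCN against cisplatin (13359 genes) the fit of 12 libraries recovered 58.2%, 71.2% and 89.2%, with 108 false calls, and a fit of the 6 libraries compared recovered 20.9%, 53.0% and 87.7%, with 16. A simulated slope of 0.75 was estimated as 0.744 and a slope of 1 as 0.976 (13350 genes). A p53 list raised 1.5-fold gave an adjusted p of 1.42e-45 in a simulated PCN against control (13350 genes), with 0 other lists called by camera. A single data set was drawn per setting. Each gene's spread in a group was taken from its 3 libraries, which estimate it poorly, so the counts of false calls are uncertain. Genes were drawn independently in all these simulations, so they cannot show how often camera calls unchanged lists whose genes vary together. In other splits of the real control and PCN libraries, camera called up to 10 lists.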

Results

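Kidney mRNA was measured in male wild-type C57BL/6 mice aged 8 weeks, in 4 groups of 3 libraries. The control group received the oil and saline vehicles. The PCN group received PCN (pregnenolone carbonitrile), a steroid that activates the rodent pregnane X receptor (PXR), a nuclear receptor that controls drug-metabolising genes, at 40 mg/kg by mouth each day. The cisplatin group received a single intraperitoneal dose of 20 mg/kg cisplatin, a platinum drug that damages the renal tubule, and the fourth group received both drugs. PCN was given for 4 days before cisplatin and for 3 days more, and tissue was taken 4 days after cisplatin. The treatment description names the cisplatin group once among the animals pretreated with PCN and once among those given oil. The groups are taken here as the library titles give them. Each library held between 18914607 and 26530485 reads assigned to genes, recovered from the deposited values. Nothing in the labels says outright that each library came from a different animal, so the p-values measure the spread between these libraries, which could be technical in part. The first principal component held 80.2% of the variance. Control and PCN libraries lay between -44.9 and -42.1 on it, cisplatin libraries between 51.2 and 62.6, and cisplatin+PCN libraries at 21.9, 40.7 and 29.3.

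The first comparison asked what cisplatin did to the kidney. Transcripts of tubular injury rose by the largest amounts, and those of proximal tubule transport fell. Havcr1 (ENSMUSG00000040405, chromosome 11, from 46735080 to 46779578), which encodes the injury marker KIM-1, rose from 0.602 ± 0.180 to 340 ± 136 FPKM (SD, n = 3). Lcn2 (ENSMUSG00000026822, chromosome 2, from 32384633 to 32388252), which encodes the iron-carrier protein NGAL, rose from 0.957 ± 0.216 to 717 ± 94.6 FPKM. Slc34a1 (ENSMUSG00000021490, chromosome 13, from 55398187 to 55415592), the main phosphate transporter of the proximal tubule, fell from 1128 ± 28.0 to 37.8 ± 6.59 FPKM. In limma's test, 8649 of 13540 genes differed between cisplatin and control (63.9%), 4330 higher and 4319 lower, of which 2072 changed at least 2-fold on the log2(FPKM + 1) scale. Coordinates here and elsewhere are those the deposited table gives, read as GRCm38, and each span is that of the whole gene.

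All 28 members of the tubular injury list rose (median log2 change 2.65, camera adjusted p = 1.51e-12; adjusted p = 0.184 with an estimated correlation). Krt20, a keratin of stressed epithelium, rose by 7.40 ± 0.54 (log2, SE). The fibrinogen chain genes Fgg, Fga and Fgb rose by 7.08, 6.35 and 5.74. Of the 32 p53 targets 30 rose and 2 fell (adjusted p = 1.85e-12; adjusted p = 0.158 with an estimated correlation). Cdkn1a, the cell-cycle inhibitor p21, rose from 2.12 ± 0.119 to 315 ± 24.5 FPKM, and the stress cytokine gene Gdf15 from 5.06 ± 0.341 to 180 ± 24.1 FPKM. Btg2, an antiproliferative gene, rose by 4.64 ± 0.23 (adjusted p = 7.37e-08 in limma's test). Of 25 cell-cycle genes 11 were tested. Of these 9 rose, among them Rrm2 (1.80), Cdc20 (1.05) and Mcm4 (0.91), and 1 fell (adjusted p = 0.00788; adjusted p = 0.286 with an estimated correlation). Among 21 regulated cell death genes 12 rose, including Acsl4 (2.20), Tnfrsf1b (1.83) and Tnfrsf1a (1.57), and 3 fell (adjusted p = 0.00889; adjusted p = 0.268 with an estimated correlation).

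Inflammatory and matrix genes also rose. Of 24 tested cytokine and NF-kB genes 22 rose and 2 did not pass (adjusted p = 4.70e-09; adjusted p = 0.164 with an estimated correlation). Complement C3 rose from 3.99 ± 0.811 to 247 ± 3.52 FPKM, and the neutrophil chemokine gene Cxcl1 from 0.411 ± 0.262 to 23.1 ± 1.75 FPKM. Saa1, an acute-phase gene with near-identical relatives, was listed at 0 in each control and PCN library and stood at 26.2 ± 11.9 FPKM with cisplatin. Ccl2, the monocyte chemokine gene, rose by 1.06 ± 0.29 (adjusted p = 0.00759 in limma's test), and Lrg1, an acute-phase glycoprotein gene, by 5.43. Tnf and Il6 stayed under the expression minimum, at 0.185 ± 0.0055 and 0.152 ± 0.0367 FPKM with cisplatin. Of 14 neutrophil genes 4 were tested and all of these rose, S100a8 by 2.21 and S100a9 by 2.36. The expression minimum can admit genes low in control because they rose, so this count is partly set by the filter. Of 13 macrophage genes 5 rose and 2 fell (adjusted p = 0.304). Of 23 matrix and fibroblast genes 15 rose, with Timp1 at 4.20 and the collagen cross-linker Lox at 3.35, and 8 did not pass (adjusted p = 0.000120; adjusted p = 0.346 with an estimated correlation).

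Tubule segment genes fell, most steeply in the proximal tubule. There 32 of 38 genes fell, 1 rose and 5 did not pass (median log2 change -2.24, adjusted p = 1.69e-09; adjusted p = 0.286 with an estimated correlation). Slc7a13, an amino acid transporter, fell from 496 ± 54.6 to 3.85 ± 1.39 FPKM. Miox, which breaks down inositol, fell by 5.29, Gatm, which makes the creatine precursor, fell by 5.28, and the endocytic receptor gene Lrp2 fell by 3.02. Slc22a2, the cation transporter that takes up cisplatin, fell from 138 ± 8.03 to 39.1 ± 3.97 FPKM, while its list of platinum handling genes split into 7 higher and 5 lower of 14 (adjusted p = 0.466). Inmt (-5.72) and Slc22a28 (-5.97) were among the 10 largest falls, as were Nat8f6 (-5.94) and Ugt2b37 (-5.21), whose multigene families leave their values uncertain. In the thick ascending limb 9 of 12 genes fell (adjusted p = 0.000237; adjusted p = 0.164 with an estimated correlation), with Egf at -4.40, Sostdc1 at -2.71 and Bsnd at -1.78. Umod, which encodes uromodulin, fell by 0.46 (adjusted p = 0.0333), a call lost without control replicate 2 (0.105), control replicate 3 (0.0881) or cisplatin replicate 1 (0.127), and with the PCN and cisplatin+PCN libraries kept out of the fit (0.0634). Of 10 distal convoluted and connecting tubule genes 9 fell (adjusted p = 0.000120; adjusted p = 0.184 with an estimated correlation), including Pvalb (-3.88), the thiazide-sensitive transporter Slc12a3 (-2.87) and Slc8a1 (-2.36). Collecting duct genes were split into 2 higher and 7 lower of 14 (adjusted p = 0.0684, and 0.0119 with a mean of -0.51 without a filter), podocyte genes into 3 and 7 of 12 (0.286), and endothelial genes into 5 and 4 of 16 (0.910).

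Mitochondrial and metabolic genes moved in different directions. Of 45 nuclear genes of oxidative phosphorylation 35 fell, 0 rose by limma's test and 10 did not pass (median -0.49, adjusted p = 2.76e-08; adjusted p = 0.397 with an estimated correlation), including Ndufs1 (-1.30), Sdha (-1.12) and Ndufs8 (-0.91). Of 13 genes encoded in mitochondrial DNA 12 fell (adjusted p = 0.00179; adjusted p = 0.358 with an estimated correlation), with mt-Atp6 at -1.36. These genes took 8.78% to 10.03% of the reads in control and PCN libraries and 6.12% to 7.81% in the libraries with cisplatin. The calls for mt-Nd4l (-1.60) and mt-Co3 (-1.45) were lost when single libraries were left out. For mt-Nd4l the adjusted p became 0.0791 without control replicate 2, 0.0998 without control replicate 3, 0.0973 without cisplatin replicate 2 and 0.0743 without cisplatin replicate 3. It was 0.0526 with the replicate block. For mt-Co3 it became 0.121 without control replicate 1, 0.0644, 0.0823 and 0.0562 without cisplatin replicates 1, 2 and 3, and 0.0763 with array weights. Ppargc1a, a driver of mitochondrial biogenesis, fell by 0.93. Genes of fatty acid oxidation and PPAR alpha went mostly the other way, with 18 of 32 higher and 5 lower (adjusted p = 0.0126; adjusted p = 0.648 with an estimated correlation). Pdk4, which holds back glucose oxidation, rose by 5.53 and Cyp4a14 by 3.35. Cholesterol synthesis genes fell in 13 of 17 cases (adjusted p = 7.71e-06; adjusted p = 0.164 with an estimated correlation), Cyp51 by -3.71, Idi1 by -2.54 and Hmgcs1 by -2.14. Of 22 Nrf2 targets 17 rose and 2 fell (adjusted p = 5.27e-05; adjusted p = 0.184 with an estimated correlation), with Cbr3 at 4.54, Srxn1 at 3.26 and Hmox1 at 2.46. Of 14 glucocorticoid-responsive genes 13 rose (adjusted p = 1.80e-05; adjusted p = 0.164 with an estimated correlation), among them Cebpd (3.47) and Mt1 (4.31), whose reads could be shared within the metallothionein family.

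Of 37 genes that PXR is known to induce 22 were tested. These rose with cisplatin in 16 of 22 cases and fell in 4 (adjusted p = 0.000436; adjusted p = 0.158 with an estimated correlation). The largest rises were in Gsta1 (4.71), uncertain because of its close relatives, Aldh1a1 (3.67) and the drug efflux pump Abcb1b (2.67). Several of these genes also answer to other receptors and to oxidative stress. Nr1i2, which encodes PXR, rose from 2.50 ± 0.378 to 5.27 ± 1.09 FPKM (adjusted p = 0.000122 in limma's test). Cyp2b10 rose from 0.125 ± 0.116 to 2.14 ± 0.406 FPKM and Cyp3a13 from 0.188 ± 0.0466 to 2.07 ± 0.554 FPKM, whereas Akr1b7 stood at 1.0 ± 0.269 and 0.768 ± 0.224 FPKM (adjusted p = 0.387). Cyp2b10 and Cyp3a13 were tested only because they passed the expression minimum in libraries with cisplatin. Of 7 erythroid genes 6 fell (median -4.66, adjusted p = 0.000843; adjusted p = 0.286 with an estimated correlation). The beta-globin gene Hbb-bs went from 366 ± 259 to 1.26 ± 1.90 FPKM, and Hba-a1 and Hbb-bt fell by 6.40 and 5.59, all members of gene families that can share reads. The remaining lists did not pass their test or had too few tested members for one. Antioxidant enzymes had 3 higher and 10 lower of 16 (adjusted p = 0.0684, and 0.0350 or 0.0306 without cisplatin+PCN replicate 1 or 2, 0.0157 without a filter and 0.0365 when rescaled without the highest and mitochondrially encoded genes). ER stress genes had 8 and 7 of 17 (0.745), circadian clock genes 5 and 6 of 14 (0.647), and adipocyte genes 2 and 0 of 9 (0.466, limma's test for the single genes, 1 higher over the list alone). Liver genes had 1 higher and 2 lower of 4. The single tested genes of the adrenal and skeletal muscle lists did not pass, and the single pancreas gene, Cela1, fell by 1.96, as did Igkc, 1 of 2 tested lymphocyte genes, by 1.45. Adjusted over the list alone, the counts differed from those over all genes in 10 lists, each by 1 member. PXR targets then had 17 higher, macrophage 4, matrix 16, fatty acid oxidation 19, circadian clock 6, adipocyte 1 and liver 2. Lower were 10 distal convoluted, 8 podocyte and 36 oxidative phosphorylation genes.

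**Figure D1:**
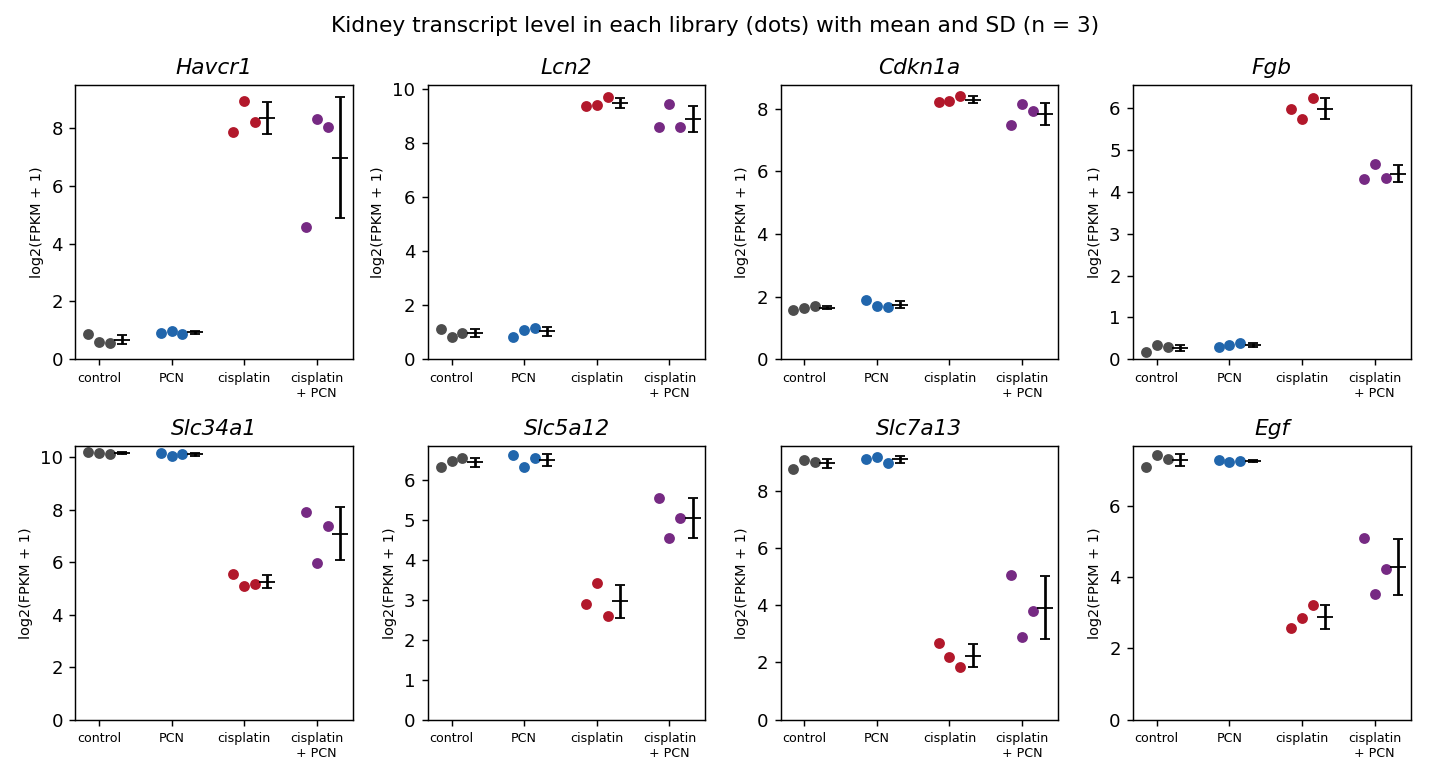
Transcript level of 8 kidney genes in each library, as log2(FPKM + 1), with dots for libraries and a bar for the mean and SD of each group (n = 3). The injury genes Havcr1, Lcn2, Cdkn1a and Fgb lie higher in both cisplatin groups than in control and PCN, and the tubule genes Slc34a1, Slc5a12, Slc7a13 and Egf lie lower.

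The second comparison asked what PCN did without injury. No gene passed. The count was 0 by limma's test (438 at an unadjusted p under 0.05, fewer than chance alone would give, smallest adjusted p 0.996) and 0 by limma-voom on recovered reads. Both fits share the larger spread of the cisplatin libraries (median within-group SD 0.149, against 0.0879 in control and PCN), which makes them cautious here. With only the control and PCN libraries in limma's fit the count was also 0. PXR target genes had a median log2 change of -0.04 over 22 tested members, 0 of which passed, also when adjusted over the list alone (adjusted p = 0.429). Cyp3a11, the classic hepatic PXR target, lay under the expression minimum, at 0.0552 ± 0.0529 FPKM in control and 0.123 ± 0.185 in PCN (SD, n = 3). Cyp2b10 stood at 0.125 ± 0.116 and 0.0679 ± 0.0276 FPKM, Cyp3a13 at 0.188 ± 0.0466 and 0.243 ± 0.0367, and Akr1b7 at 1.0 ± 0.269 and 1.31 ± 0.493. Nr1i2 stood at 2.50 ± 0.378 and 2.29 ± 0.241 FPKM, and Nr1i3, which encodes the related receptor CAR, at 0.0521 ± 0.0238 and 0.0756 ± 0.0272. The other genes of the fixed panel had differences between -0.31 (Ccl2) and 0.25 (Havcr1), none past the threshold in limma's test.

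As a set, 17 genes of ER stress and protein folding were lower with PCN (median -0.20, adjusted p = 1.47e-06; adjusted p = 0.0472 with an estimated correlation), the 1 list of 26 that passed under both settings. By limma's test 0 of its members passed over all genes, and 6 were lower when adjusted over the list alone. Those 6, picked after their values were seen, encode chaperones and folding factors. They are Sdf2l1 (-0.82), Creld2 (-0.49), Hspa5 (-0.40), Calr (-0.40), Pdia4 (-0.29) and Hsp90b1 (-0.27), and Hspa5 went from 146 ± 7.35 to 111 ± 6.49 FPKM. With the preset correlation 6 other lists passed. Genes of fatty acid oxidation (mean 0.17; adjusted p = 0.949 with an estimated correlation) and mitochondrially encoded genes (0.24; adjusted p = 0.949 with an estimated correlation, and 0.0529 without a filter) were higher as sets, and injury genes (-0.17; adjusted p = 0.949 with an estimated correlation) were lower. The calls of the other 3 were also lost when single libraries were left out. For oxidative phosphorylation (mean -0.04; adjusted p = 0.949 with an estimated correlation) the adjusted p was 0.696 without control replicate 1, 0.0713 and 0.126 without PCN replicates 1 and 3, and 0.0581 without cisplatin replicate 2. For collecting duct (-0.13; adjusted p = 0.230 with an estimated correlation) it was 0.144 without control replicate 2, and 0.0643 and 0.102 without PCN replicates 1 and 2. For podocyte genes (0.06; adjusted p = 0.949 with an estimated correlation) it was 0.998 without control replicate 3, 0.109 and 0.102 without PCN replicates 1 and 2, 0.0538, 0.0601 and 0.0510 without cisplatin replicates 1, 2 and 3, and 0.0517 without cisplatin+PCN replicate 3. Some lists that had no call gained one. Macrophage genes did without control replicate 1 (0.00412), PCN replicate 2 (0.0250), cisplatin+PCN replicate 1 (0.0151) or 3 (0.0421), with the replicate block (0.0202) and with median-of-ratios rescaling (0.0489), and distal convoluted tubule genes without control replicate 3 (0.0266) or PCN replicate 1 (0.0338). Erythroid genes did without control replicate 2 (mean -0.54, 0.0009) or 3 (-0.42, 0.0266), with a mean of 0.19 without control replicate 1. Matrix genes did without control replicate 1 (0.0254), Nrf2 targets without PCN replicate 2 (0.0455) or cisplatin replicate 3 (0.0452), and adipocyte genes, lower with PCN, without PCN replicate 1 (mean -1.21, 6.41e-10). The mean log2(FPKM + 1) of the adipocyte genes stood apart in control replicate 1 (3.20) and PCN replicate 1 (3.76), against 0.88 to 1.85 in the other control and PCN libraries. Adjusted over the list alone, 1 injury gene was lower, and 1 cytokine gene was higher and 1 lower.

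The third comparison asked how the injured kidney differed when PCN was also given. With cisplatin+PCN, 15 of 38 proximal tubule genes were higher than with cisplatin alone, and 16 of 28 injury, 6 of 23 matrix and 7 of 11 cell-cycle genes were lower. These 4 lists passed camera's test with the preset correlation and lost their calls with an estimated one (adjusted p = 0.406, 0.383, 0.406 and 0.383 with an estimated correlation, in the same order). Slc5a12 (ENSMUSG00000041644, chromosome 2, from 110597298 to 110647779), a lactate transporter of the proximal tubule, stood at 7.05 ± 2.39 FPKM with cisplatin and 33.6 ± 12 with both drugs, against 87.3 ± 6.77 in control (SD, n = 3). Fgb (ENSMUSG00000033831, chromosome 3, from 83040141 to 83049863) stood at 63.6 ± 11.5 and 20.8 ± 3.05 FPKM, against 0.201 ± 0.0663 in control. In limma's test 2110 genes passed, 1079 higher and 1031 lower, of which 127 changed at least 2-fold. On simulated data this fit made 108 false calls beside 39, 47 and 58 recovered genes that had been changed 1.5-, 2- and 4-fold. A fit of only the 6 libraries compared made 16, beside 14, 35 and 57. The adjusted p-values of single genes in this comparison may thus not hold the rate of false calls that their threshold names. The simulation took each gene's spread from 3 libraries per group, so the size of the excess is uncertain. The count depended on the control and PCN libraries in the fit, which share the estimate of the spread and raise its degrees of freedom from 6.65 to 10.9. With only the 6 libraries compared in the fit, 1 gene passed, the microRNA gene Mir343 (log2 change -1.62, adjusted p = 0.0292), named after its value was seen. In that fit 3094 of 13540 genes had an unadjusted p under 0.05 by limma's test, more than chance alone would give on average.

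Of 38 proximal tubule genes 15 were higher, 0 were lower by limma's test and 23 did not pass, and adjusted over the list alone 23 were higher (median 0.75, adjusted p = 4.51e-09; adjusted p = 0.406 with an estimated correlation). The mean log2(FPKM + 1) of this list was 5.54, 5.30 and 5.16 in the cisplatin libraries. It was 6.72, 5.51 and 6.08 in the cisplatin+PCN libraries, so the groups overlapped. The median change lay between 0.492 and 0.983 when 1 library was left out. Slc5a12 rose by 2.09 ± 0.24 (log2, SE, adjusted p = 0.00221) and Lrp2 by 1.03 ± 0.16. Slc34a1 rose by 1.83 ± 0.36, to 156 ± 89.0 FPKM (adjusted p = 0.0132, and 0.0508 without cisplatin+PCN replicate 3), and Slc7a13 by 1.67 (0.0260, and 0.0969 without cisplatin replicate 3 or 0.0676 without cisplatin+PCN replicate 3). Keg1 (2.63), the organic anion transporter gene Slc22a22 (1.65) and Tmem52b (1.80) rose, as did Nat8f6 (1.87) and Nat8f1 (1.66) of a multigene family. Hacl1, a peroxisomal lyase of fatty acid alpha-oxidation, was at 9.89 ± 1.35 FPKM in control, 12.5 ± 0.442 with cisplatin and 46.8 ± 31.6 with both drugs, where its libraries stood at 83.2, 25.7 and 31.4 FPKM. Thick ascending limb genes were higher in 7 of 12 cases, or 10 adjusted over the list alone (adjusted p = 7.69e-06; adjusted p = 0.335 with an estimated correlation). Egf rose by 1.40 (adjusted p = 0.0173, and 0.0582 without cisplatin replicate 1 or 0.0540 without cisplatin+PCN replicate 3). Umod differed by 0.48 (adjusted p = 0.0800). Of 10 distal convoluted and connecting tubule genes 6 rose, Slc12a3 by 1.14 (adjusted p = 0.000215; adjusted p = 0.383 with an estimated correlation). Of 14 collecting duct genes 7 rose and 2 fell (adjusted p = 0.0211, and 0.0902 without cisplatin+PCN replicate 2; adjusted p = 0.335 with an estimated correlation), with the glucocorticoid-inactivating Hsd11b2 at 1.09, the anion exchanger Slc4a1 at 0.98 and the sodium channel subunit Scnn1g at 0.82. Podocyte genes rose in 3 of 12 cases, or 4 with 1 lower over the list alone (adjusted p = 0.0306, and 0.0771 without cisplatin replicate 1 or 0.0687 without cisplatin+PCN replicate 2; adjusted p = 0.425 with an estimated correlation).

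Injury genes fell in 16 of 28 cases, or 20 adjusted over the list alone, and 0 rose by limma's test (median -0.69, adjusted p = 3.64e-10; adjusted p = 0.383 with an estimated correlation). The mean log2(FPKM + 1) of this list was 6.27, 6.46 and 6.54 with cisplatin and 5.01, 6.03 and 5.74 with both drugs, without overlap. Among lists called here, chosen on these same libraries, only proximal tubule, oxidative phosphorylation and fatty acid oxidation overlapped in this mean. Fgb fell by 1.56 ± 0.13 (adjusted p = 0.000337) and Sprr2f by 1.76 (0.0190, and 0.0602 without cisplatin replicate 1). Krt20 was at 243 ± 33.9 FPKM with cisplatin and 83.9 ± 62.2 with both drugs (adjusted p = 0.0388). That call was lost without any 1 of 9 libraries, with an adjusted p of 0.0527, 0.0556 and 0.0533 without control replicates 1, 2 and 3, 0.0536, 0.0561 and 0.0572 without PCN replicates 1, 2 and 3, 0.0877 and 0.120 without cisplatin replicates 1 and 3, and 0.0672 without cisplatin+PCN replicate 3. Havcr1 did not pass (340 ± 136 against 202 ± 158 FPKM, adjusted p = 0.238), and its cisplatin+PCN libraries were at 22.8, 321 and 262 FPKM. Lcn2 (-0.61, adjusted p = 0.0711), Cdkn1a (-0.46, 0.0532) and Gdf15 (-0.57, 0.123) did not pass either, though each did without cisplatin+PCN replicate 2 (0.00334, 0.0115 and 0.00641), and Cdkn1a did with limma-voom (0.0435). Of 32 p53 targets 4 fell and 2 rose (adjusted p = 0.000952; adjusted p = 0.406 with an estimated correlation), Btg2 by -1.08 (0.0156, and 0.0548 without cisplatin replicate 3 or 0.0588 without cisplatin+PCN replicate 3). Adjusted over the list alone, 8 fell and 2 rose. Lox fell by 1.55 among 6 of 23 matrix genes that fell, 10 over the list alone (adjusted p = 3.51e-06; adjusted p = 0.406 with an estimated correlation). The endothelial adhesion gene Sele (-1.21) and the macrophage growth factor gene Il34 (-0.76) were among 9 of 24 cytokine and NF-kB genes that fell, 12 over the list alone (adjusted p = 1.48e-05; adjusted p = 0.388 with an estimated correlation). Ccl2 differed by -0.55 (adjusted p = 0.208). Of 11 cell-cycle genes 7 fell, or 9 with 1 higher over the list alone (adjusted p = 9.29e-05; adjusted p = 0.383 with an estimated correlation), Ube2c by -0.68 (adjusted p = 0.0153, and 0.0505 without cisplatin replicate 3). Serpina3n (-1.37) and Serpina3m (-1.38), of a family with near-identical members, and Lgi2 (-1.43) also fell.

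Of 45 nuclear oxidative phosphorylation genes 6 rose, 5 over the list alone, and 39 did not pass (median 0.17, adjusted p = 7.69e-06; adjusted p = 0.575 with an estimated correlation), Ndufs8 by 0.41. The mean log2(FPKM + 1) of this list was 7.19, 7.10 and 7.19 in the cisplatin libraries. In the cisplatin+PCN libraries it was 7.50, 7.15 and 7.32, so the groups overlapped. Of 17 cholesterol synthesis genes 5 rose and 1 fell (adjusted p = 0.0137; adjusted p = 0.425 with an estimated correlation), Mvd by 0.66. Fatty acid oxidation genes rose in 4 of 32 cases, 1 over the list alone, with Ppargc1a at 0.44 (adjusted p = 0.0211; adjusted p = 0.712 with an estimated correlation). Their call was lost without cisplatin replicate 2 (0.350) or cisplatin+PCN replicate 1 (0.913, mean -0.04). Glucocorticoid-responsive genes fell in 2 of 14 cases (adjusted p = 0.0137, and 0.0671 without cisplatin replicate 3; adjusted p = 0.406 with an estimated correlation). These were the metallothionein genes Mt1 (-0.89, adjusted p = 0.0169, and 0.0673 without cisplatin replicate 3) and Mt2 (-0.71, adjusted p = 0.0459). The call for Mt2 was lost without control replicates 1, 2 or 3 (0.0588, 0.0645 and 0.0617), PCN replicate 3 (0.0662), cisplatin replicates 1, 2 or 3 (0.120, 0.0526 and 0.120) and cisplatin+PCN replicates 1 or 3 (0.108 and 0.0900). Among 22 PXR targets 1 rose and 2 fell, or 3 over the list alone (adjusted p = 0.882; the median of 0.06 and the mean of -0.04 differed in sign). Cyp2b10 was at 2.14 ± 0.406 FPKM with cisplatin and 0.905 ± 0.512 with both drugs (adjusted p = 0.0260, and 0.0632, 0.0983 or 0.0596 without cisplatin replicate 1, cisplatin replicate 3 or cisplatin+PCN replicate 3). Cyp3a13 was at 2.07 ± 0.554 and 1.27 ± 0.213 FPKM (0.0546, and 0.00534 without cisplatin replicate 2), Nr1i2 at 5.27 ± 1.09 and 4.68 ± 0.218 (0.472) and Akr1b7 at 0.768 ± 0.224 and 0.824 ± 0.271 (0.890). Slc22a2 rose by 0.75 (adjusted p = 0.0118), while its platinum handling list had 3 higher and 3 lower of 14 (0.882). Erythroid genes, down with cisplatin, differed by a median of -0.18 between the 2 cisplatin groups, with 0 of 7 past limma's test (adjusted p = 0.845). Cell death genes fell in 5 of 21 cases, 6 over the list alone (adjusted p = 0.112, and 0.0371, 0.0437 or 0.0454 without cisplatin replicate 1, cisplatin replicate 3 or cisplatin+PCN replicate 2, and 0.0467 without a filter). Macrophage genes fell in 3 of 13 cases, 4 over the list alone (adjusted p = 0.118, and 0.0344, 0.0290 or 0.0216 without cisplatin replicate 3, cisplatin+PCN replicate 2 or cisplatin+PCN replicate 3, and 0.0152 without a filter). Nrf2 targets fell in 4 of 22 cases, or 6 with 2 higher over the list alone (adjusted p = 0.0737, and 0.00211 or 0.0193 without cisplatin replicate 3 or cisplatin+PCN replicate 3, and 0.0258 without a filter). Circadian clock genes had 1 higher and 1 lower of 14 (0.381, and 0.0371 without cisplatin replicate 2). The ER stress list, lower with PCN alone, did not pass here, with 0 higher and 3 lower of 17 (median -0.18, adjusted p = 0.267; adjusted p = 0.575 with an estimated correlation). By limma's test 0 of 13 mitochondrially encoded genes (0.158) and 0 of 16 antioxidant genes (0.205) passed, although as lists both did without cisplatin+PCN replicate 2 (0.00811 and 0.00982), and the antioxidant list did with quantile normalization (0.0215).

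The count of 2110 moved with single libraries. It was 580 without cisplatin replicate 3, 805 without cisplatin replicate 1, 3390 without cisplatin replicate 2, 1175 without cisplatin+PCN replicate 1 and 596 without cisplatin+PCN replicate 3. Of the 59 named genes that passed, 24 kept their call without each library in turn, and 59 lost it with only the 6 libraries in the fit. Some missed the threshold narrowly in that fit. By limma's test the adjusted p was 0.0947 for Fgb and Nat8f6, 0.0991 for Nat8f1 and 0.111 for Slc5a12, but 0.177 for Cpt2. Fgb, Nat8f6, Nat8f1 and Slc5a12 lost their call in this comparison under no other alternative.

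**Figure D2:**
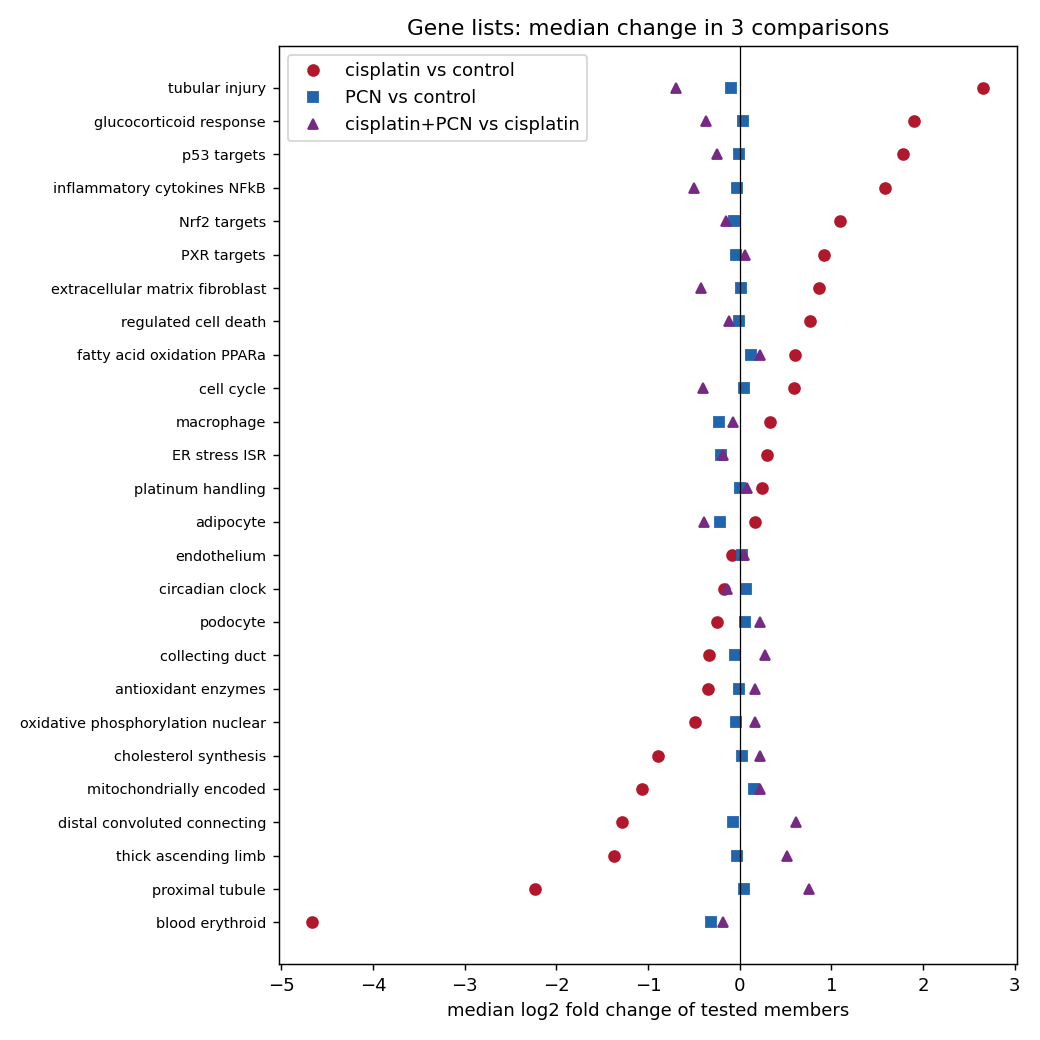
Median log2 change of the tested members of each gene list in 3 comparisons, with circles for cisplatin against control, squares for PCN against control and triangles for cisplatin+PCN against cisplatin. The tubular injury list lies at 2.65 for cisplatin and -0.69 for cisplatin+PCN against cisplatin, and the proximal tubule list at -2.24 and 0.75.

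The cisplatin response was also measured within the PCN-treated animals. Against PCN alone, 6352 genes differed with cisplatin+PCN (3178 higher, 3174 lower), and against control 6308 did (3110 higher, 3198 lower), by limma's test. Injury genes rose in 26 of 28 cases against PCN and in 22 against control, or 27 and 25 adjusted over the list alone. The p53 targets rose in 29 of 32 cases in both, and proximal tubule genes fell in 30 and 29 of 38, or 32 and 31 over the list alone. With an estimated correlation no list passed in either (0 of 26 by camera, against 16 in each with the preset value; the smallest adjusted p = 0.0776 and 0.0742 with an estimated correlation). Of 5784 genes called in the cisplatin effects without and with PCN, 5775 went the same way. Across genes, the effect with PCN was 0.742 of that without on the log2 scale, a slope corrected for error in the x values. Genes are not independent replicates, so no p is given for the slope. Leaving out each library gave slopes from 0.689 to 0.781.

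**Figure D3:**
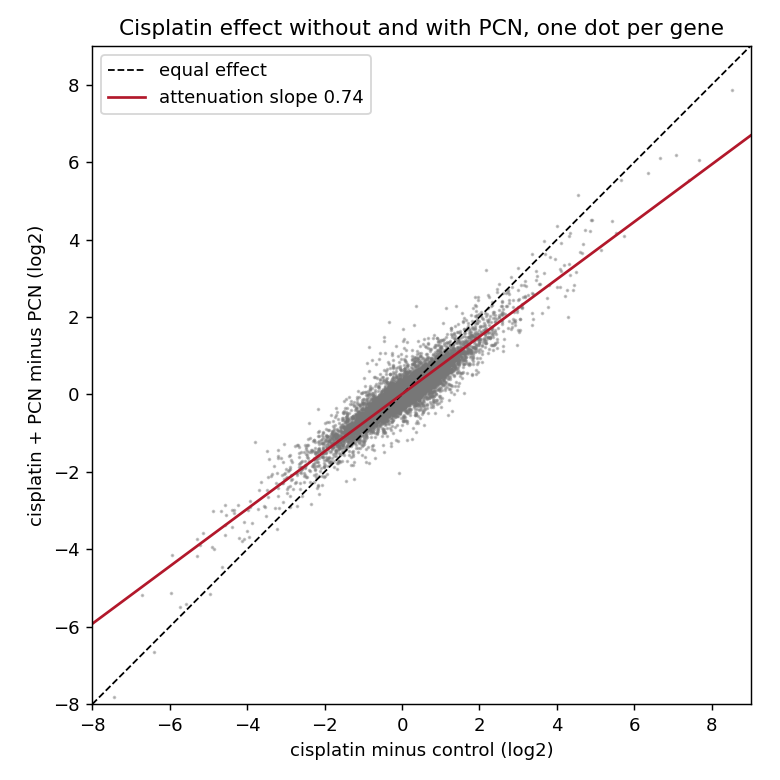
Log2 change with cisplatin in animals without PCN (horizontal axis, cisplatin minus control) and with PCN (vertical axis, cisplatin+PCN minus PCN), with 1 dot per gene for 13540 genes. The dashed line marks an equal effect, and the solid line has the slope of 0.74 given in the text.

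Genes moved by cisplatin and by the addition of PCN overlapped in opposite directions. Of 1978 genes called in both, 1955 went opposite ways (98.8%) and 23 the same way. There were 970 genes up with cisplatin and down with PCN added, and 985 the other way round. Independent lists would share 330 and 344, but both changes use the same cisplatin libraries with opposite sign, so these are not the counts that no change would give. In 100 simulations that kept the cisplatin effect and set cisplatin+PCN equal to cisplatin, the counts averaged 7.54 and 8.1, with 18 the highest of each, and in simulated unchanged groups 1.30 and 1.13. Calls in the same direction averaged 10.3 with the effect kept, with 26 the highest, where 29.5 genes on average were called between cisplatin+PCN and cisplatin. The observed 23 came from 2110 such calls, so the 2 counts have unlike bases and are not compared. Genes were drawn independently, without the variation that genes of a real library share. At most 62 genes were called there between cisplatin+PCN and cisplatin, against up to 1245 in other splits of the 6 real libraries. Those splits mix the groups unevenly and keep a part of any real difference, so 1245 is not a count for no change either. The simulated counts may be too low by an unknown amount, and are not read as what no change would give. The correlation across genes was -0.75, against -0.52 in simulated unchanged groups, and the covariance was -0.205 against -0.0162. Those groups hold no cisplatin effect, so shared libraries alone set their correlation. The correlation for a kept cisplatin effect with nothing changed by PCN was not simulated, so -0.52 is not a part of -0.75. The cisplatin libraries were then split, 1 against 2, so that the changes shared none, a setting chosen after the data were seen. Over the 6 such splits the correlation lay between -0.69 and -0.54 and the covariance between -0.228 and -0.152. The counts of opposite calls varied widely, from 2 and 2 with cisplatin replicates 1 and 3 used for the cisplatin effect to 1099 and 1131 with cisplatin replicate 2 used for it, and the calls in the same direction numbered 0 and 72 in these splits.

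The interaction, which tests whether the cisplatin effect itself differed with PCN, passed for 15 genes (10 higher, 5 lower, limma's test) of 2617 at an unadjusted p under 0.05. Fgb (-1.63), the protease inhibitor gene Pi15 (-1.39), the lipid droplet gene Plin2 (-1.32), the translation repressor gene Eif4ebp1 (-1.10) and the claudin gene Cldn3 (-1.07) had a smaller rise with PCN. The call for Fgb was not made by limma-voom (adjusted p = 0.116). Plin2 stood at 25.4 ± 2.26 FPKM in control, 28.0 ± 1.21 with PCN, 596 ± 107 with cisplatin and 259 ± 3.17 with both (SD, n = 3). Slc13a2, the dicarboxylate transporter that reabsorbs citrate, had a smaller fall with PCN (1.23), at 17.3 ± 1.67, 20.3 ± 1.30, 4.69 ± 0.749 and 14.5 ± 1.24 FPKM in the same order. So had Nat8f6 (1.78) and Nat8f1 (1.72), uncertain as members of a family. Arhgef19 (1.33, adjusted p = 0.0311) and Tmem52b (1.77, 0.0311) lost their call when single libraries were left out. Without control replicates 1, 2 and 3, PCN replicates 1, 2 and 3, cisplatin replicate 3 and cisplatin+PCN replicates 1 and 3, in that order, the adjusted p was 0.0842, 0.0675, 0.104, 0.0882, 0.0706, 0.0822, 0.0805, 0.0537 and 0.119 for Arhgef19. It was 0.0842, 0.0909, 0.0870, 0.0882, 0.107, 0.131, 0.0532, 0.0519 and 0.0931 for Tmem52b. Arhgef19 also lost it without cisplatin replicate 1 (0.109), and with the replicate block both did (0.0771 and 0.101). The count was 1066 without cisplatin replicate 2, 493 without cisplatin+PCN replicate 2 and 9 without cisplatin+PCN replicate 3.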

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

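The tests of scaling, of single libraries and of borrowed spread and the shares of genes without overlap in this part were chosen after the results were seen, and the counts over other splits of the libraries were planned before.

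The cisplatin effect differed with PCN, by the interaction test, for the genes Nat8f6 (1.78), Tmem52b (1.77), Nat8f1 (1.72), Arhgef19 (1.33), Slc13a2 (1.23), Fgb (-1.63), Pi15 (-1.39), Plin2 (-1.32), Eif4ebp1 (-1.10) and Cldn3 (-1.07), as log2 differences of the effects. Among gene lists, camera with the preset correlation called the differences for tubular injury (mean -0.66), matrix (-0.63), cell cycle (-0.45), cytokines and NF-kB (-0.40), glucocorticoid response (-0.34) and p53 targets (-0.25). It also called proximal tubule (0.72), thick ascending limb (0.68), distal convoluted and connecting tubule (0.65), collecting duct (0.43), cholesterol synthesis (0.24) and nuclear oxidative phosphorylation (0.21). With an estimated correlation 0 of these 12 lists passed (smallest adjusted p = 0.103). Over 100 drawn splits of the libraries, 15 gave as many genes as the real count of 15, and the highest other split gave 203. For lists 37 of 100 splits gave as many as the real 12, the highest other 17. Chance is not excluded for either count. Why a split called many more genes than the real one was not tested.

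The first pattern is the smaller cisplatin response in animals that also had PCN. A scaling factor per library, which moves all genes the same way, is argued against as the whole cause, since between cisplatin and cisplatin+PCN the median of the proximal tubule list was higher (0.75, jackknife spread 0.29) and that of the injury list lower (-0.69, spread 0.24), 1.44 apart. Both lists had already been called in this comparison, so their opposite signs were known when they were chosen. A single cisplatin+PCN library as the whole cause is argued against too, the highest slope without 1 of them being 0.781, below 1 by more than the jackknife spread of 0.0776. Jackknife spreads came from leaving out each library in turn, combined within groups for the list medians and over all 12 libraries for the slope. A protective action of PCN, a milder injury in these animals for another reason, and a smaller dose reaching the kidney stay open, and none of these was tested. With 3 libraries per group, the spread between libraries limits how well a drug effect can be separated from a response that may vary between animals.

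The second pattern is the 2110 genes called between cisplatin+PCN and cisplatin. Only 1 gene was called when the 6 libraries compared made up the fit, which leaves the log2 changes as they were, as a spread borrowed from the quieter control and PCN libraries would give. The median within-group SD was 0.149 in the cisplatin groups and 0.0879 in the others, and the degrees of freedom went from 10.9 to 6.65, so the loss may also come in part from fewer libraries. The 10 splits of these 6 libraries are too few for a share under 0.05, with 2110 genes for the real split (1 split as large) and 1245 for the highest other, and the groups did not overlap for 29.4% of all 13540 genes, against 24.7% in the highest other split and 10% by chance. The other splits mix the groups unevenly and keep a part of any real difference, so their values do not stand for no change. On simulated data the fit of 12 libraries made 108 false calls and that of the 6 libraries 16, though that simulation took each gene's spread from 3 libraries per group. The count of 2110 may thus hold more false calls than its threshold allows for, while a difference between the groups stays open.

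For the remaining counts the 10 splits are likewise too few for a share under 0.05. The real and the highest other count of genes were 8649 and 0 for cisplatin against control (1 split as large), 0 and 2 for PCN against control (10), 6308 and 1 for cisplatin+PCN against control (1), and 6352 and 0 for cisplatin+PCN against PCN (1). For PCN against control 438 genes had an unadjusted p under 0.05 by limma's test. There limma-voom also called 0, as did limma with only the control and PCN libraries in the fit. The counts of lists were 17 and 18 (2), 7 and 10 (3), 16 and 16 (2), and 16 and 17 (3) in the same order, and 14 and 16 (3) for cisplatin+PCN against cisplatin.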

How the results depend on the processing

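All alternatives here were planned but the split of the cisplatin libraries, chosen after the data were seen. The counts for cisplatin+PCN against cisplatin and for the interaction depended most on the setting. Without a filter, which adds low genes to the test, PCN against control had 2 genes and cisplatin+PCN against cisplatin 1008. At a mean FPKM of at least 5, where 7469 genes were tested, cisplatin against control had 5197, cisplatin+PCN against control 4000, cisplatin+PCN against PCN 4031 and the interaction 30. The interaction had 24 when rescaled without the highest and mitochondrially encoded genes, and the cause was not tested. With only the groups compared, which leaves fewer libraries, cisplatin+PCN against cisplatin had 1. Array weights gave 6862 for it, 9555 for cisplatin+PCN against PCN and 4315 for the interaction, with a weight of 20.1 on cisplatin+PCN replicate 3 against 0.229 to 1.58 on the others, and are not read as evidence. With an estimated correlation, camera called 0 lists in cisplatin against control, 1 in PCN against control, and 0 in the other 4 comparisons.

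Leaving out 1 library gave 580 (without cisplatin replicate 3) to 3390 (without cisplatin replicate 2) genes for cisplatin+PCN against cisplatin and 9 (without cisplatin+PCN replicate 3) to 1066 (without cisplatin replicate 2) for the interaction. No other count moved by over 1.5 times in this way. The erythroid list in PCN against control, not called with all libraries, had means from -0.54 to 0.19, the positive value without control replicate 1 (adjusted p = 0.0341). The cause was not tested. The slope stayed between 0.739 and 0.752 over the other settings. The correlation of -0.75 between the cisplatin effect and the change with PCN added became -0.69, -0.62 and -0.67 with cisplatin replicate 1, 2 or 3 alone used for the cisplatin effect and the others for the second change, and -0.61, -0.54 and -0.66 the other way round, where no shared library adds to it. No call of a named gene was reversed under any alternative, while some genes without a call changed sign. In PCN against control these were Cyp2b10 (-0.27 to 0.09), Krt20 (-0.25 to 0.07), Lcn2 (-0.02 to 0.16), Umod (-0.04 to 0.13), Ppargc1a (-0.04 to 0.10) and Slc22a2 (-0.07 to 0.01), and in cisplatin+PCN against cisplatin Akr1b7 (-0.25 to 0.14) and Nr1i2 (-0.33 to 0.01). Without a filter the calls for Umod (0.116), mt-Nd4l (0.0730) and mt-Co3 (0.0742) in cisplatin against control and for Slc7a13 (0.0688), Krt20 (0.0972), Sprr2f (0.0533), Mt2 (0.113) and Cyp2b10 (0.0608) in cisplatin+PCN against cisplatin were lost, as were those of Tmem52b (0.102) and Arhgef19 (0.107) for the interaction. A pseudocount of 0.1 ended the calls of Krt20 (0.0587), Mt2 (0.350) and Cyp2b10 (0.117). The call for Mt2 was also lost with a pseudocount of 0.5 (0.0922), with rescaling without the highest and mitochondrially encoded genes (0.0761), with the replicate block (0.0770) and with limma-voom (0.0756), and that for Cyp2b10 with limma-voom (0.0537). Other genes set by the rule lost calls in these settings too. At a mean FPKM of at least 5 the cell death list in cisplatin against control (0.0523), the podocyte (0.178) and oxidative phosphorylation (0.0557) lists in PCN against control and the collecting duct (0.0916) and podocyte (0.164) lists in cisplatin+PCN against cisplatin lost their calls. The podocyte list also lost its call in cisplatin+PCN against cisplatin with quantile normalization (0.0537), and in PCN against control with a pseudocount of 0.1 (0.0511) or without a filter (0.0959). These are adjusted p-values of limma and camera.

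Whether equal replicate numbers pair the libraries was not decided. Of 18 same-number pairs 4 had deviations correlated over 0.1, and the range was -0.28 to 0.37, with no pairs of different numbers set beside them. Between cisplatin and cisplatin+PCN the correlation was 0.37, 0.24 and -0.28 for replicates 1, 2 and 3. With the replicate block, cisplatin+PCN against cisplatin had 1675 genes, cisplatin against control 8455 and the interaction 14. Depth limits genes near the expression minimum most, since an FPKM of 1 rests on 18.7 to 27.2 reads per kilobase.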

Other observations

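The tests of over-representation, of scaling and of blood left in the tissue in this part were chosen after the results were seen.

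Some genes were higher with both drugs than with either cisplatin alone or neither drug. There were 70 such genes, past limma's test against control and against cisplatin, and 35 were lower in both, where the same direction in cisplatin against control was not required. Among the 70 were Hacl1 (1.63 against cisplatin, 1.95 against control), the sulfate transporter gene Slc13a1 (1.41 and 1.27), the glycine-degrading Gldc (0.99 and 2.11), and Ugt1a2 (1.08 and 3.25), uncertain because of shared exons in its gene family. These were picked after their values were seen. The calls share the limits of cisplatin+PCN against cisplatin, where the fit made 108 false calls on simulated data and 1 gene, which was lower, passed with only the 6 libraries compared. A hypothesis that fatty acid oxidation genes are over-represented among the 70 was not decided, with 1 of 32 (Cpt2) among them where 0.165 was expected (Fisher's exact p = 0.153, two-sided). Against cisplatin, Cpt2 lost its call in 13 of 23 alternatives. The adjusted p was 0.0539, 0.0568 and 0.0536 without control replicates 1, 2 and 3, 0.0557, 0.0574 and 0.0593 without PCN replicates 1, 2 and 3, 0.0722 and 0.137 without cisplatin replicates 1 and 3, and 0.0827 and 0.105 without cisplatin+PCN replicates 1 and 3. It was 0.0939 without a filter, 0.0502 with the replicate block and 0.177 with only the 6 libraries, by limma's test.

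The third pattern is the loss of haemoglobin transcripts with cisplatin. Hbb-bs was at 663, 183 and 253 FPKM in the control libraries and at 3.45, 0 and 0.335 in the cisplatin libraries. Median-of-ratios factors lay between 0.989 and 1.02 over the 12 libraries, too near 1 for such scaling to account for a fall of this size. The median change of the called erythroid genes, closest to 0 over 3 other scalings, was -5.07. That value adds no support, since the genes were chosen by their call in this comparison and factors so near 1 could hardly move it. Less blood left in the tissue may contribute and cannot be told apart here from fewer young red cells in the blood, since the tested neutrophil genes rose (median 2.10) and neutrophils entering an injured kidney would hide a loss of blood. Only 4 of 14 neutrophil genes were tested, and the expression minimum can admit genes low in control because they rose. An effect of cisplatin on the bone marrow was not tested.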
